A study of Homo sapiens with 8 samples.

How the data were processed

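RNA immunoprecipitated from Daoy medulloblastoma cells was hybridised to 8 two-colour Agilent arrays with 41000 probes on 43376 spots other than controls. Per the labels, each array set RNA from an Msi1 RIP against RNA from a control RIP, with a treatment time of 48 h, after antibody-coated beads, washing, proteinase K digestion and phenol/chloroform extraction. Per the labels' protocols, labelled cRNA was made with Agilent's linear amplification kit for low RNA input. The labels put the arrays into 2 biological replicates of 4 arrays each, with Msi1 RNA in Cy5 on a pair of arrays and in Cy3 on the other pair. Each ratio was turned to Msi1 RIP over control RIP by the dyes in the labels. The labels name an Msi1 antibody and a prebleed antibody, the series text a tagged Msi1 and a tagged control construct, and which RIP was used is not settled by these sources.

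The spot and background values are intensities on a linear scale, made by Agilent Feature Extraction, version 9.5.1.1 per the file headers and version 8.5 per the submitters' processing notes. Per the file headers, the deposited processed intensities were spatially detrended, dye-normalized by linear and LOWESS steps with a smooth factor of 0.25, and replaced by surrogates where low. The deposited log ratio of each spot, log10 of red over green processed signal per the file headers, was not used in the tests. The authors' deposited table of normalized values is on a log2 scale, red over green by its name. The names of its columns do not tie them to samples, so it was described only. Each of its 8 columns correlated with a single array at 0.9998 to 1.000 across probes, after loess as described here, with medians from -0.01 to 0.02. A correlation does not depend on scale or offset, so the scale rests on the table's name and the centring on these medians. Its normalization method is not given in the sources used here. Genome positions are those of the array files, whose headers name hg18.

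From the mean spot intensities and the local background medians, the background was corrected with normexp and an offset of 50, and each array was normalized by loess with control and outlier spots at weight 0 (limma 3.58.1, R 4.3.3). Loess sets the typical log ratio at each brightness to 0, so a change shared by most transcripts is removed. Outlier spots and control spots were left out and saturated spots were kept. Spots of a probe were averaged. A probe was tested if it was well above background in either channel on at least 4 of 8 arrays, and a gene was represented by its probe of highest mean intensity. Of the 18964 genes tested, 12273 were named through RefSeq accessions, 853 by a current symbol and 386 by an older symbol of the GRCh38.p14 gene table, and 5452 kept the files' name. Of 5425 genes with further tested probes, 135 had probes at least 1 log2 unit apart and 10 had probes on opposite sides beyond 0.5, and the values of genes with exactly 2 probes correlated at 0.690 across 4104 genes.

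The 4 arrays of a biological replicate share their RNA and were averaged, orientation by orientation, to 1 value per replicate. These 2 values were tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 19.3 degrees of freedom and an SD of 0.139, so the SE of a gene rests mainly on the spread pooled over genes. The dye effect was fitted with limma on the 4 means of orientation and replicate. Slide and scan coincided with the biological replicate, so no block for them could be fitted apart from it. As the labels name 1 group of ratios, no other split of the arrays was tested.

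The genes named were chosen by a rule fixed before the data were examined. It took MSI1, MSI2 and the reported targets whatever their values, the 12 largest positive and the 12 largest negative ratios among genes past the threshold with the same sign on all 8 arrays and a current symbol, and from each gene list up to 4 members of smallest p, 2 per direction where there were. Some members chosen this way are not reported here. The 23 lists, 870 entries in all, were written before the data were examined. They covered Msi1 and its paralogue, reported Msi1 targets, apoptosis, cell cycle, extracellular matrix, focal adhesion, hedgehog, Notch, Wnt, receptor tyrosine kinase with PI3K and MAPK signalling, interferon response, stress and immediate early genes, neural stem cells, RNA-binding proteins, translation factors, ribosomal proteins, proteasome, oxidative phosphorylation, mitochondrially encoded transcripts, replication-dependent histones, housekeeping genes, and markers of blood cells and of liver and epithelium. A list with at least 5 genes tested was set against all other genes with limma's camera at a preset correlation of 0.01, and adjusted over the lists.

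The test was tried on simulated data with the real number of genes and 200 changed genes. It recovered 86.6% of changes of 0.5 log2 units and 100% of changes of 1 and of 2 log2 units. Over 20 simulated sets the share of false calls was 1.69% to 17.6% with a median of 12.6%, and it was 19.1% in a set with the measured array noise added on top, so an aim of under 10%, set before the simulation, was not met. In 7 of the 20 sets the prior's degrees of freedom were estimated as infinite, although the sets were drawn with 19.3. Estimates of them from 2 values per gene were thus imprecise in these sets. Among unchanged simulated genes 4.55% to 6.07% had an unadjusted p under 0.05. The simulation changed 200 of 18964 genes, whereas 5033 were called enriched and 4396 depleted in the data, and it held no control shared by the replicates. Its shares of recovered and false calls therefore do not carry over to the calls in the data.

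Alternatives fixed beforehand were Agilent's processed signals with loess or with median centring, median centring without loess, Aquantile normalization between arrays, an offset of 10, no filter and a stricter filter on dim probes, the mean of a gene's probes, either dye orientation alone, each array or each replicate left out, all 8 arrays with the replicate as a random block or as if independent, an intensity trend with a robust prior, a 2-fold threshold, an estimated correlation in camera, and 10000 random lists matched on intensity. Scaling to the spike-in controls, recentring on the genes tested, an estimated correlation on all 8 arrays and the dye effect under other normalizations were added after seeing the data. The spike-in shift was taken from the signals before normalization, chosen over the spike-in values after loess (-1.21 and -1.09 in the replicates) once both had been seen, because it varied less over spike-ins. A search for Msi1 motifs in 3' UTRs needs transcript sequences that were not used here.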

Results

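Musashi1 (Msi1) is an RNA-binding protein of neural stem and progenitor cells. RNA that came down with it was measured in Daoy, an established human medulloblastoma cell line, by RNA immunoprecipitation followed by microarray hybridisation (RIP-chip). On each of 8 two-colour Agilent arrays the RNA of an Msi1 RIP was hybridised together with the RNA of a control RIP, with a treatment time of 48 h. The arrays came from 2 biological replicates, each hybridised on 4 arrays, with Msi1 RNA in Cy5 on a pair of them and in Cy3 on the other pair. The array labels describe an Msi1 antibody against a prebleed antibody, whereas the series text describes cells given a tagged Msi1 construct or a tagged control construct, and both sources are kept here side by side. The series text speaks of a single control sample, so the replicates may share it, and the p-values then leave out the control's own spread. Of 41000 probes, 55.8% to 69.0% were well above background in the Msi1 RNA and 39.9% to 72.7% in the control RNA of an array. The number of arrays, which stand for 2 replicates, limits the precision. Values are log2 ratios of Msi1 RIP over control RIP with the typical transcript of each array at 0, so that enriched and depleted mean relative to that transcript. They are means of n = 2 replicates with the limma standard error (SE), and adjusted p-values are limma's with Benjamini-Hochberg adjustment.

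The first comparison asked which transcripts came down with Msi1 more, or less, than with the control. Of 18964 genes tested, 5033 (26.5%) were enriched in the Msi1 RIP and 4396 (23.2%) were depleted, while 9535 did not pass. Most of these shifts were small with the processing used: 421 genes were enriched and 316 depleted by at least 2-fold. The ratios ran from -1.17 at the 1st percentile to 1.22 at the 99th. The offset of 50 exceeded the median net control signal (9.59 to 31.6) except on arrays of replicate 2 with Msi1 in Cy3 (271 and 274). Ratios of dim transcripts may thus be drawn towards 0. With Agilent's processed signals and loess the median of genes named ZNF was 0.29 against 0.15, and of genes named RPL -0.26 against -0.29. How the 2-fold counts depend on the offset was not tested. The most enriched transcript encoded ATP6V1G1, a subunit of the proton pump that acidifies lysosomes, at 2.46 (SE 0.11), which is 5.51-fold. The most depleted was ZSWIM9 at -2.28 (SE 0.12).

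Among the 12 most enriched transcripts, ATP6V1G1 was followed by COX1, a mitochondrially encoded subunit of cytochrome c oxidase, at 2.21 (SE 0.10) and by TMEM230 at 2.16 (SE 0.10). The membrane protein TSPAN3 stood at 2.11 (SE 0.13) and the splicing factor SRSF3 also at 2.11 (SE 0.10). The secreted glycoprotein FSTL1, the syndecan-binding adaptor SDCBP and ARPP19, an inhibitor of the mitotic phosphatase PP2A, each stood at 1.99. The ubiquitin-conjugating enzyme UBE2E3 reached 1.96, ARL6IP1 and the sialomucin CD164 each reached 1.95, and PCLAF, which binds the replication clamp PCNA, reached 1.94. By the rule of choice all 12 were positive on all 8 arrays, with adjusted p-values from 8.94e-12 to 1.56e-10. For several of these genes the array carried further probes. Those of TMEM230 gave 1.51 to 2.07 and those of UBE2E3 and ARL6IP1 gave 1.74 and 2.37, but the other probe of SDCBP gave 0.22, that of CD164 gave 0.72 and that of ARPP19 gave 1.16. The ATP6V1G1 probe lies at chromosome 9, 116399966 to 116400025, the SRSF3 probe at chromosome 6, 36678402 to 36678461, and the UBE2E3 probe at chromosome 2, 181636288 to 181636347, in the coordinates of the array files (hg18). The COX1 probe is placed by the files on chromosome 1, 557430 to 557489, so that a nuclear copy of the mitochondrial gene cannot be set apart from it.

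Among the 12 most depleted transcripts, TAF15, an RNA-binding protein, stood at -2.15 (SE 0.10), and the hnRNP protein HNRNPA3 at -1.84 (SE 0.10). GAR1, a component of box H/ACA particles, stood at -1.86 (SE 0.11), and FBL (fibrillarin), the methyltransferase of box C/D particles, at -1.79 (SE 0.13). NEAT1, the nuclear noncoding RNA that builds paraspeckles, was at -1.79 (SE 0.10). ZSWIM9 was followed by PPDPF at -2.03 (SE 0.16), FKBP2, a prolyl isomerase of the endoplasmic reticulum, at -1.92 and the prefoldin subunit PFDN6 at -1.80. PLEKHS1 was also at -1.80, the small GTPase RAB13 at -1.77 and the endoplasmic reticulum protein SDF2L1 at -1.75. By the same rule of choice all 12 were negative on all 8 arrays, with adjusted p-values from 8.94e-12 to 1.76e-08. The replicates lay furthest apart for PPDPF, at -1.44 and -2.63, and for SDF2L1, at -1.18 and -2.33. The second FBL probe gave -1.97, the 8 probes of HNRNPA3 ran from -0.21 to -1.84, and the other probes of NEAT1 and PLEKHS1 gave -0.60 and -0.79. The TAF15 probe lies at chromosome 17, 31198107 to 31198166, the FBL probe at chromosome 19, 45016973 to 45017032, and the NEAT1 probe at chromosome 11, 64949850 to 64949909 (hg18).

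**Figure D1:**
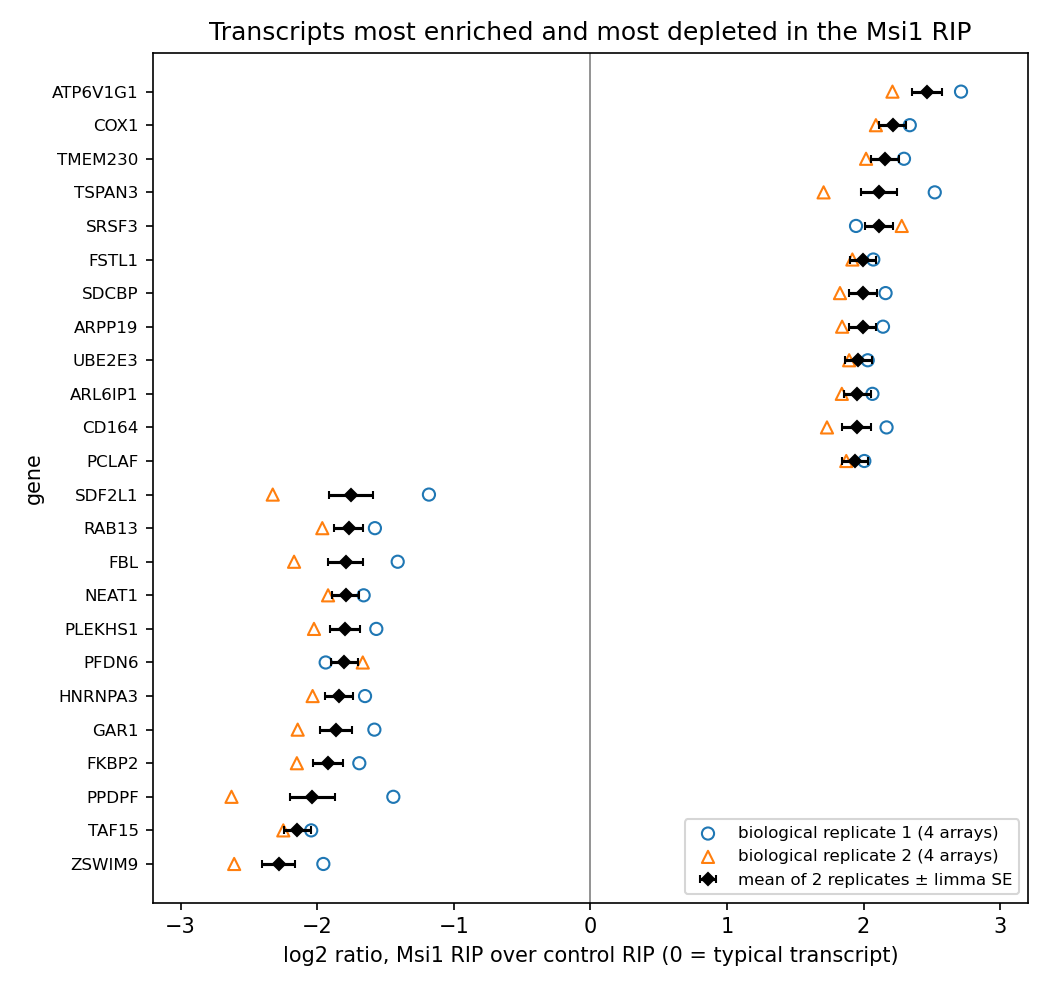
Log2 ratio of Msi1 RIP over control RIP (horizontal axis) for the 12 most enriched and the 12 most depleted genes (vertical axis). Diamonds are means of the 2 biological replicates with the limma SE as bars, circles and triangles are each replicate's mean over 4 arrays, and both replicates lie on the same side of 0 for each of these genes, from ATP6V1G1 at 2.46 to ZSWIM9 at -2.28.

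The ratios of the biological replicates had a Pearson correlation across genes of 0.899 and a Spearman correlation of 0.879. Genes are not independent replicates, and a control RNA shared by the replicates would raise this correlation. Between single arrays the correlation across genes was 0.899 to 0.970 for repeat arrays of a replicate in the same dye orientation and 0.747 to 0.865 for opposite orientations of a replicate. Between replicates it was 0.806 to 0.853 in the same orientation and 0.753 to 0.811 in opposite ones. Opposite orientations of replicate 2, at 0.747 to 0.770, thus differed more than arrays of different replicates in the same orientation. Of the enriched genes 4530, and of the depleted genes 3665, had the same sign on all 8 arrays. Each biological replicate lay on a slide of its own, so replicate and slide cannot be told apart.

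The counts of enriched and depleted genes depend on the normalization. Without the intensity-dependent loess normalization, centring each array on the median of its spots gave 10727 enriched and 1380 depleted genes, so that 88.6% of the calls were enriched against 53.4% with loess. Taken relative to the median of the genes tested, a choice made after seeing the data, the values without loess gave 6948 enriched and 7243 depleted genes, with 1978 of the 4396 depleted calls kept and 734 calls opposite to those with loess, so that more than the place of 0 differs. Without loess the medians of bins of genes of like brightness had an SD of 0.62 log2 units, against 0.033 with loess. Values without loess, here and below, thus hold a large trend with brightness. Agilent's processed signals with the same centring gave 7643 and 3119, or 71.0% enriched, and scaling to the spike-in controls, chosen after seeing the data, gave 18684 and 19.

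The second comparison read out the transcripts of Msi1 itself, of its paralogue and of targets reported for it in earlier work. The MSI1 transcript did not pass the test at -0.056 (SE 0.10, adjusted p = 0.659). MSI2, the closely related family member, was depleted at -1.02 (SE 0.11, adjusted p = 1.07e-07). Among the reported targets, the transcript of the Notch inhibitor NUMB was enriched at 0.66 (SE 0.10, adjusted p = 9.46e-06). That of the cyclin-dependent kinase inhibitor CDKN1A (p21) was enriched at 0.30 (SE 0.10, adjusted p = 0.0143).

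The axon guidance receptor ROBO3 was depleted at -0.67 (SE 0.10, adjusted p = 1.83e-05), but lost the call without loess at -0.28 (adjusted p = 0.0615). APC, of the complex that destroys beta-catenin, did not pass at -0.14 (SE 0.10, adjusted p = 0.249) and was depleted at -1.06 (adjusted p = 1.99e-13) without loess, and DCX was not tested because its probe was too dim. Adjusted over the list alone, 2 of the 4 reported targets tested were enriched and 1 was depleted, the same numbers as over all genes. The probe for MSI1 lies at chromosome 12, 119264593 to 119264652, that for MSI2 at chromosome 17, 53112021 to 53112080, that for NUMB at chromosome 14, 72812262 to 72812321, and that for CDKN1A at chromosome 6, 36762684 to 36762743 (hg18). Whether the MSI1 probe falls within a transfected construct was not examined. The control RNA was well above background at the MSI1 probe on 1 of 8 arrays and the Msi1 RNA on 8, and MSI1 was depleted at -0.50 (adjusted p = 0.0183) with Agilent's processed signals and loess and at -0.86 (adjusted p = 2.47e-09) without loess. Other dim genes were also low without loess, among them CD14 at -0.88 and HP at -0.87, markers of other cell types. The values of MSI1 and APC without loess thus cannot be told apart from the trend with brightness. The 2nd probe of CDKN1A gave -0.17 and the mean of its probes 0.063 (adjusted p = 0.574), and it also lost the call with processed signals, with loess or with median centring, and with Msi1 in Cy5 alone (0.18 to 0.24), while the other probes of MSI2 and ROBO3 kept the sign at -0.25 and -0.31.

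The third comparison asked whether groups of genes, fixed before the data were examined, moved together in the Msi1 RIP. Transcripts for cell cycle regulators and for receptor tyrosine kinase, PI3K and MAPK signalling were shifted upwards, as were the mitochondrially encoded transcripts. Transcripts for the nuclear-encoded subunits of oxidative phosphorylation, for ribosomal proteins and for replication-dependent histones were shifted downwards. The medians of oxidative phosphorylation and ribosomal proteins turned positive without loess (0.23 and 0.42), where a trend with brightness remains. Of the 21 lists with at least 5 genes tested, these 6 passed in limma's camera test with a preset correlation of 0.01 between genes. None of the 6 passed when the correlation was estimated from the 2 replicate values (adjusted p = 0.936 with an estimated correlation for each). With 2 values per gene that test has too few degrees of freedom to decide, and it gave 0.936 or more for all 21 lists. Signalling also had 0.936, although its estimated correlation of -0.020 lay below the preset one. With a correlation estimated on all 8 arrays, chosen after seeing the data, the 6 lists had adjusted p-values from 0.191 to 0.606.

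Of 51 cell cycle genes, 25 were enriched and 7 depleted, with a median of 0.23 (camera adjusted p = 0.00516; adjusted p = 0.936 with an estimated correlation). The transcription factor E2F3, at 1.03, and WEE1, the kinase that restrains entry into mitosis, at 1.00, were enriched, while E2F1 was depleted at -0.56. The cyclin-dependent kinase inhibitor CDKN2D was depleted at -0.48. Of 48 receptor tyrosine kinase, PI3K and MAPK genes, 26 were enriched and 8 depleted, with a median of 0.27 (camera adjusted p = 0.0119; adjusted p = 0.936 with an estimated correlation). MET, the receptor for hepatocyte growth factor, stood at 1.34 (SE 0.10), with 0.67 and 0.78 at its other probes. The receptor ERBB2 and the kinase MAP2K2 were depleted at -0.70 and -0.63. The MET probe lies at chromosome 7, 116225526 to 116225585 (hg18). The shift of the signalling list did not pass with Agilent's processed signals and loess (median 0.34, adjusted p = 0.0721) nor on the arrays with Msi1 in Cy5 (median 0.19, adjusted p = 0.0654). With processed signals and median centring neither list passed (medians 0.21 for the cell cycle and 0.33 for signalling, adjusted p = 0.159 for both).

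Among 74 nuclear-encoded genes of oxidative phosphorylation, 47 were depleted and 9 enriched, with a median of -0.42 (camera adjusted p = 5.29e-08; adjusted p = 0.936 with an estimated correlation), a direction that turned without loess to 0.23 (adjusted p = 0.0634). UQCR11, a small subunit of complex III, stood at -1.32, with -0.22 at its other probe, and ATP5F1E of the ATP synthase at -1.26, whereas COX7C of complex IV and NDUFB3 of complex I were enriched at 0.97 each. Of 78 ribosomal protein genes, 42 were depleted and 5 enriched, with a median of -0.26 (camera adjusted p = 1.51e-05; adjusted p = 0.936 with an estimated correlation), and this direction turned without loess to 0.42 (adjusted p = 0.00133). RPS29 and RPS21 were depleted at -1.30 and -1.17, while RPL26 and RPL15 were enriched at 1.60 and 1.28. Of 44 replication-dependent histone genes, 22 were depleted and 2 enriched, with a median of -0.25 (camera adjusted p = 2.23e-04; adjusted p = 0.936 with an estimated correlation; without loess -0.041, adjusted p = 0.361; -0.13 without replicate 1). H4C11 and H4C8 were depleted at -1.01 and -0.76, and H3C3 and H3C1 were enriched at 0.52 and 0.43, of which H3C1 lost the call with Msi1 in Cy3 alone (0.24, adjusted p = 0.205) and with processed signals and median centring (0.34, adjusted p = 0.0885). Histone genes are near-identical copies whose probes may share targets, so their single values are uncertain. Values without loess are given relative to the median of the genes tested, which lay at 0.58 in that setting.

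Of 6 mitochondrially encoded transcripts tested, 4 were enriched and 2 did not pass, with a median of 0.87 (camera adjusted p = 0.00256; adjusted p = 0.936 with an estimated correlation; processed signals with median centring 0.84, adjusted p = 0.0724). Besides COX1, cytochrome b (CYTB) stood at 1.09 (SE 0.10), ND1 at 1.01 (SE 0.11) and ND2 at 0.74 (SE 0.10). ND3 and ND6, named after their values were seen, did not pass at 0.15 and 0.092. The files give no position for the probes of CYTB, ND1 and ND2.

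The remaining lists did not pass as groups in the main test, although many of their members did. Without loess, the lists of RNA-binding proteins (median 0.65, adjusted p = 1.93e-05), translation factors (0.65, adjusted p = 4.30e-05), focal adhesion (0.39, adjusted p = 0.00108), extracellular matrix (0.42, adjusted p = 0.00734), Wnt (0.52, adjusted p = 0.0122) and apoptosis (0.22, adjusted p = 0.0219) passed upwards and that of liver and epithelial markers downwards (-0.85, adjusted p = 0.0219). Of 52 genes for RNA-binding proteins, 24 were enriched and 12 depleted (median 0.24, and 0.11 without replicate 1; camera adjusted p = 0.187). The STAR protein KHDRBS1 (Sam68) stood at 1.15 and the poly(C)-binding protein PCBP2 at -1.28. Of 40 Wnt pathway genes, 16 were enriched and 7 depleted (median 0.14, adjusted p = 0.0985, and adjusted p = 0.0112 without a filter on dim probes). TCF7L2, a transcription factor of the pathway, stood at 1.57, with 0.32 and 0.36 at its other probes, and the secreted antagonist SFRP1 at 1.06. PORCN, which acylates Wnt ligands, and the receptor FZD2 were depleted at -0.52 and -0.50. Of 36 Notch pathway genes, 10 were enriched and 6 depleted (median 0.012, turning to -0.033 without replicate 1; adjusted p = 0.837). Alongside NUMB, the coactivator MAML1 was enriched at 0.67, while HES4 and the gamma-secretase subunit APH1B were depleted at -0.64 and -0.63. Of 20 hedgehog pathway genes, 7 were enriched and 3 depleted (median 0.038, adjusted p = 0.799), among them the co-receptor GAS1 at 1.00, the kinase CSNK1A1 at 0.78 with 0.28 to 0.55 at its other probes, the receptor component SMO at -0.70 and the protein kinase A subunit PRKACA at -0.69 with -0.087 at its other probe. Of 28 neural stem cell genes, 9 were enriched and 4 depleted (median 0.10, and 0.16 without replicate 1; adjusted p = 0.584). The transcription factor SOX2 stood at 0.79, with 0.22 at its other probe, and the filament protein VIM (vimentin) at 0.78, whereas the related SOX3 stood at -1.36 and SOX1 at -1.32, with -0.44 and 0.0040 at their other probes.

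Of 35 apoptosis genes, 14 were enriched and 9 depleted (median 0.049, and 0.078 without replicate 2; camera adjusted p = 0.681). Both directions held members of the BCL2 family. BCL2L11 (BIM), which promotes apoptosis, stood at 1.19, with 0.28 to 0.35 at its other probes, and MCL1, which restrains it, at 1.14, with 0.54 and 1.00. The proapoptotic BBC3 (PUMA) stood at -1.33, with -0.21 and -0.35 at its other probes, and BAX at -1.11. Of 41 focal adhesion genes, 11 were enriched and 7 depleted (median 0.0012, adjusted p = 0.584), including the GTPases RAC1 at 1.91 and RHOA at 0.99 and the adaptors ZYX at -0.64 and PXN at -0.49. The other probes of RAC1 gave 0.76 and 0.87, those of RHOA 0.36 and 0.88, and those of PXN -0.065 and -0.0066, and the mean of the PXN probes did not pass (-0.19, adjusted p = 0.0881). Of 40 extracellular matrix genes, 10 were enriched and 13 depleted (median 0.086, turning to -0.028 without replicate 1; adjusted p = 0.980), including CCN2 at 1.75, the crosslinking enzyme LOX at 0.80, the protease inhibitor TIMP1 at -0.68 and the proteoglycan BGN at -0.63. Of 28 interferon response genes, 8 were enriched and 9 depleted (adjusted p = 0.837), with a median of 0.0024 while the mean of -0.0039 and the test pointed down. GBP1 stood at 0.81, ISG15 at -0.98 and IFI27 at -0.67, with -0.41 at the other IFI27 probe. Of 35 stress and immediate early genes, 6 were enriched and 11 depleted (median -0.035, adjusted p = 0.681), including EGR2 at 0.63, FOS at 0.55, HSF1 at -0.64 and HMOX1 at -0.43. Without loess the median of the stress genes was 0.46 (adjusted p = 0.0122).

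Of 45 translation factor genes, 9 were enriched and 9 depleted (adjusted p = 0.837), with a median of 0.0045 and a mean of 0.022 while the test pointed down. The helicase EIF4A2 stood at 1.43, with 1.01 and -0.10 at its other probes, and the cap-binding protein EIF4E at 0.91, with 0.56 and 0.63, while EIF5B and EIF3J stood at -0.71 and -0.68. Of 40 proteasome genes, 8 were enriched and 15 depleted (median -0.18, adjusted p = 0.115, adjusted p = 0.0487 with Msi1 in Cy5 alone and adjusted p = 0.0413 with the preset correlation over all 8 arrays), a direction that turned without loess to 0.49 (adjusted p = 7.36e-04). PSMD6 and PSMD10 were enriched at 1.09 and 0.74, and PSMB3 and PSMD7 were depleted at -0.82 and -0.64. Of 27 housekeeping genes, 8 were enriched and 10 depleted (median -0.083, adjusted p = 0.681), which also turned without loess to 0.59 (adjusted p = 7.84e-04). HPRT1 and PGK1 were enriched at 0.84 and 0.80, with 0.38 to 0.65 at the other PGK1 probes, while FTL and TMSB10 were depleted at -0.89 and -0.78. Markers of other cell types were mostly too dim to test. Of 24 blood cell markers, 5 were bright enough to test and 1 was depleted, CD4 at -0.32 (-0.22 with Msi1 in Cy5 alone, adjusted p = 0.116), while CD79A at 0.19, CD14 at 0.0051 and CD68 at -0.12 did not pass (median -0.0010, adjusted p = 0.799). CD79A was enriched at 0.48 with Msi1 in Cy5 alone (adjusted p = 0.00339) and at 0.74 without loess (adjusted p = 2.71e-07), where CD14 was depleted at -0.88 (adjusted p = 9.89e-10). Of 24 liver and epithelial markers, 10 were tested and 2 were depleted, the keratin KRT8 at -0.42 and MUC1 at -0.25, while SERPINA1 at -0.19 and HP at -0.17 did not pass (median -0.14, and -0.079 without replicate 2; adjusted p = 0.227). MUC1 lost its call in 6 settings at values of -0.26 to -0.21 (adjusted p = 0.0601 to 0.176), KRT8, whose other probe gave -0.21, lost it with Msi1 in Cy3 alone (-0.19, adjusted p = 0.280), and HP, whose control RNA was well above background on 4 of 8 arrays, was depleted at -0.49 with processed signals and loess (adjusted p = 0.0325) and at -0.87 without loess (adjusted p = 1.60e-09).

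The named list members that were called here had adjusted p-values from 8.94e-12 to 0.0429, with an SE close to 0.10. Adjusted over the list alone, the enriched and depleted counts were 26 and 7 for the cell cycle, 27 and 8 for receptor tyrosine kinase signalling, 11 and 50 for oxidative phosphorylation, and unchanged for ribosomal proteins, histones and mitochondrially encoded transcripts. They were 27 and 12 for RNA-binding proteins, 14 and 14 for the extracellular matrix, 9 and 18 for the proteasome, 7 and 4 for hedgehog, 8 and 11 for both housekeeping and stress genes, 9 and 8 for translation factors, and 0 and 1 for liver and epithelial markers. For the other lists they equalled the counts over all genes. Without loess, the depleted values of CDKN2D, ZYX, PXN, CD4, KRT8, PSMD7, MAP2K2, HSF1, PORCN and FZD2 turned positive, between 0.016 and 0.24, and did not pass. Those of TIMP1, SMO, PRKACA, FTL, TMSB10, PSMB3, HMOX1 and EIF3J stayed negative, between -0.24 and -0.013, and did not pass either.

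**Figure D2:**
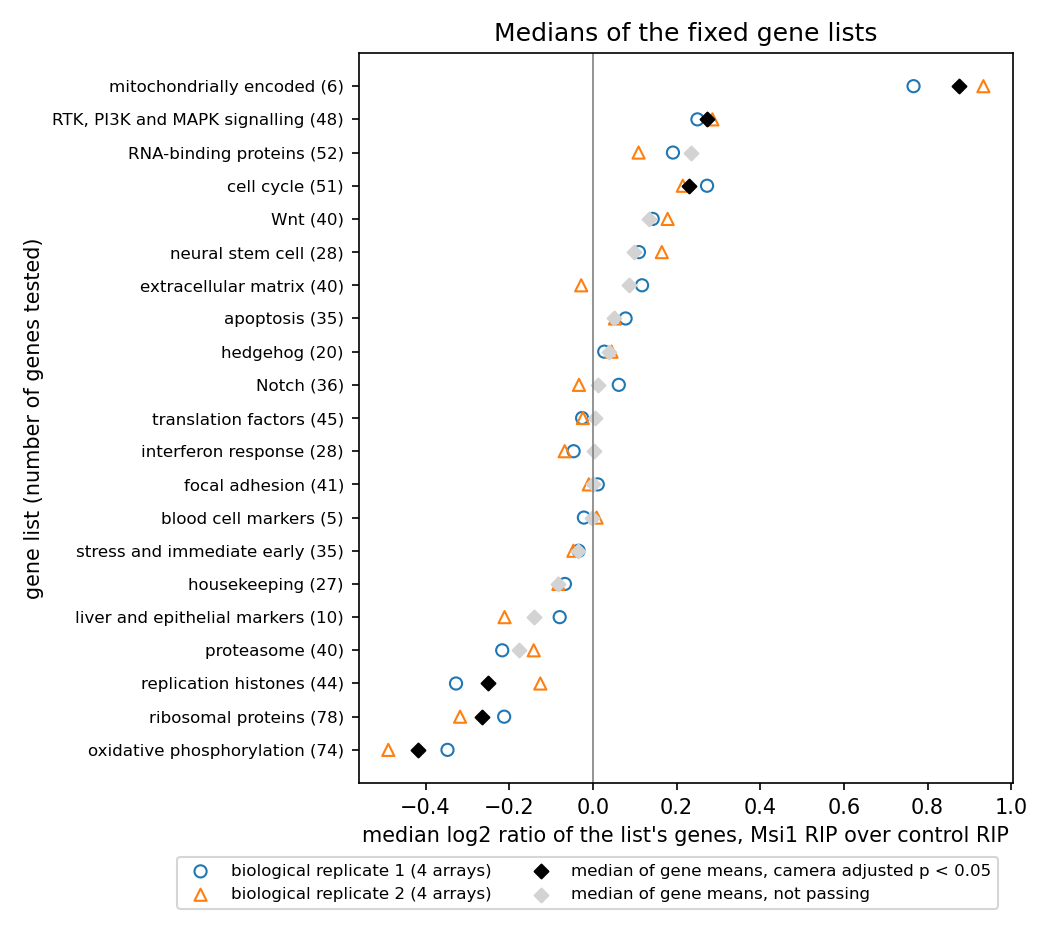
Median log2 ratio of Msi1 RIP over control RIP (horizontal axis) of each of the 21 gene lists with at least 5 genes tested, with the number of genes tested in brackets (vertical axis). Diamonds are medians of the gene means, black where camera with a preset correlation passed, and circles and triangles are medians per biological replicate over 4 arrays. They run from -0.42 for oxidative phosphorylation to 0.87 for mitochondrially encoded transcripts, and the medians of oxidative phosphorylation, ribosomal proteins, proteasome, housekeeping and stress genes turn positive without loess (0.23, 0.42, 0.49, 0.59 and 0.46).

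As technical checks, dye bias and the spike-in controls were examined. In a limma fit over the 4 means of dye orientation and replicate, 0 genes showed a dye effect after adjustment and 1299 did at an unadjusted p under 0.05. A fit on 4 means has few degrees of freedom, so the count of 0 does not show that dye bias was absent. The median size of the dye effect was 0.070, against 0.24 for the Msi1 effect. The Cy5 over Cy3 ratios of the 10 spike-in probes after loess correlated between arrays at 0.922 to 1.00 across spike-ins, in the same and in opposite orientations. A correlation does not show an offset, and the ratios themselves differed between orientations. In replicate 1, E1A_r60_1 stood at -1.62 and -1.75 with Msi1 in Cy5 and at 0.88 with Msi1 in Cy3. Over the 9 spike-ins used for scaling, the mean ratio of Msi1 over control after loess was -1.21 and -1.09 in the replicates.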

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

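The tests on brightness in the first paragraph were chosen only after the result was seen. Before any normalization the Msi1 RNA was brighter than the control RNA, by 4.98-fold in summed signal on the slide of replicate 1 and 5.01-fold on that of replicate 2, when both dye orientations were averaged. Single arrays of replicate 1 had log2 ratios of 1.94 to 2.71. Those of replicate 2 had 5.85 and 5.52 with Msi1 in Cy5, but -1.26 and -0.80 with Msi1 in Cy3, where the control RNA was brighter. The 5.01-fold is thus a mean over values of opposite sign. The spike-in controls, which enter none of the tests of genes with loess and hold no cellular RNA, were also brighter in the Msi1 channel, by a mean log2 ratio of 1.01 over the slides. A difference in scanner gain or dye would cancel between the orientations if it was the same on all arrays of a slide. The median gene spot kept a log2 ratio of at least 2.32 on either slide. More labelled cRNA loaded from the Msi1 RIP would move genes and spike-ins alike, and the spike-ins moved by 0.91 on replicate 1 and 1.12 on replicate 2. The genes exceeded the spike-ins by at least 1.25 log2 units, with an SD over spike-ins of 0.095 on replicate 1 and 0.041 on replicate 2. This argues against loading as the only cause, while the part shared with the spike-ins stays open to it. That more RNA was recovered with Msi1 from a larger set of bound transcripts may account for the excess of up to 1.41, and this cannot be told apart from unequal amounts of spike-in or a different amplification yield, because the amounts added are not known.

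Of 139 values checked for a single array that stood apart from the other 7 of the 8 arrays, 7 did so. Chance would give 6.95 at 1 in 20 if the arrays were independent. They are repeats within 2 replicates and 2 dye orientations, so that rate may not hold and the likeness of the numbers decides nothing. NUMB stood at 0.16 on an array of replicate 2 with Msi1 in Cy5, against 0.57 to 0.85 on the others. On the same array 1 spot was saturated, against 0 on each of the others, and the median of the mitochondrially encoded transcripts was 1.11, against 0.68 to 0.87. HES4 stood at -0.33 on an array of replicate 1 with Msi1 in Cy5, against -0.75 to -0.58, and RPS29 at -1.005 on the other array of that kind, against -1.41 to -1.26. On an array of replicate 2 with Msi1 in Cy3, 72.7% of probes were well above background in the control RNA, against 39.9% to 51.4%. On that array the median of the stress and immediate early genes was -0.20, against -0.079 to -0.0097.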

How the results depend on the processing

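Counts of enriched and depleted genes stayed within 1.5 times of 5033 and 4396 under most settings, among them 4519 to 5127 and 3956 to 4506 without each array in turn, and 7057 and 6260 with all 8 arrays and the replicate as a random block. The exceptions were median centring without loess (10727 and 1380), Agilent's processed signals with median centring (7643 enriched) and a 2-fold threshold (421 and 316). Chosen after seeing the data, taking the values without loess relative to the median of genes tested gave 6948 and 7243, with 734 calls opposite to the main ones, and scaling to the spike-in controls gave 18684 and 19. Spike-in scaling moves the 0 of the scale, and a 2-fold threshold leaves fewer genes, by construction, while median centring without loess also keeps trends with intensity. As the setting that gave the 734 differs from the main one only in the loess step and the place of 0, they come from these. Median centring moved the median of the genes tested to 0.58 without loess and to 0.24 with processed signals. Named genes and lists are therefore given relative to that median, a choice made after seeing that 32 of 112 named genes and 7 of 21 lists reversed without it in the first case, and 1 and 4 in the second. MSI1 became depleted at -0.50 with processed signals and loess and at -0.86 without loess, where other dim genes were also low. The correlation between replicates was 0.868 with processed signals and median centring, against 0.899, and the cause of these changes was not tested.

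Of 111 other named genes, 85 kept their direction and call under the settings that were compared gene by gene, which leave out plain median centring, spike-in scaling, the 2-fold threshold, the intensity trend and the fits on all 8 arrays. With a replicate left out no call could be tested. There, only a turned direction of a called gene could count as a change. Without loess CDKN2D stood at 0.12, ZYX at 0.016, PXN at 0.19, CD4 at 0.24, KRT8 at 0.24, PSMD7 at 0.044, MAP2K2 at 0.037, HSF1 at 0.039, PORCN at 0.020 and FZD2 at 0.038, all reversed. With processed signals and median centring APC stood at 0.077, and with Msi1 in Cy3 alone CD79A stood at -0.092, whereas without loess APC was depleted at -1.06 and CD79A enriched at 0.74. CD14, at 0.0051 with loess, stood at -0.28 with processed signals and loess, -0.0092 with Msi1 in Cy5 alone, -0.88 without loess, -0.030 with processed signals and median centring, and -0.033 to 0.043 without each array or replicate. CDKN1A lost its call in 4 settings and MUC1 in 6.

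None of the 21 lists was unchanged in median, direction and call under every alternative. Without loess the lists of oxidative phosphorylation (0.23), ribosomal proteins (0.42), proteasome (0.49), housekeeping (0.59) and stress genes (0.46) reversed, and hedgehog (-0.019) and interferon genes (-0.14) did so from medians near 0. Other reversals also started from medians near 0. Focal adhesion stood at -0.065 with processed signals and loess, -0.019 with an offset of 10, -0.060 with the stricter filter, -0.016 with the mean of a gene's probes, -0.022 with Msi1 in Cy5 and -0.13 with processed signals and median centring. Interferon genes stood at -0.19 with processed signals and loess, -0.12 with the stricter filter, -0.019 with Msi1 in Cy5, -0.0054 with Msi1 in Cy3 and -0.14 with processed signals and median centring. Hedgehog stood at -0.011 with Msi1 in Cy3 and -0.050 with processed signals and median centring, translation factors at -0.043 in both, and Notch at -0.0094 without a filter. Without each array or replicate, focal adhesion ranged from -0.023 to 0.025, interferon from -0.067 to 0.026, blood markers from -0.033 to 0.027, stress genes from -0.047 to 0.011 and translation factors from -0.026 to 0.014, and the extracellular matrix stood at -0.028 and Notch at -0.033 without replicate 1. The reversals without loess come from leaving out the loess step and from the place of 0, and the cause of the others was not tested. With a correlation estimated from all 8 arrays, chosen after seeing the data, the 6 lists that passed had adjusted p-values from 0.191 to 0.606. Among 10000 random lists matched on intensity, the medians of oxidative phosphorylation, histones and ribosomal proteins lay at the 0, 0.01 and 0.27 percentiles, and those of cell cycle, mitochondrially encoded and signalling genes at the 98.5, 99.9 and 99.95 percentiles, but RNA-binding proteins, which did not pass, lay at 99.5 and liver and epithelial markers, which did not either, at 2.18.

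The authors' deposited table was not run as an alternative because the names of its columns do not tie them to samples. A slide or scan block was not run because each slide held 1 biological replicate. No paired analysis was possible because the arrays form a single group of ratios. Signal limits MSI1, APC and CD14, whose control RNA was well above background on 1 of 8 arrays.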

Other observations

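The gene families in this paragraph, their tests and, below, the comparison of zinc-finger genes and the test for an intensity trend were chosen only after the data were seen. Among 118 families of at least 12 genes that share the start of a name, nucleoporins had the smallest p. With a correlation estimated from the 2 replicate values the adjusted p was 0.995 for every family, so that test cannot decide between them. Estimated on all 8 arrays, it was 0.330 for nucleoporins. Of 22 nucleoporin genes (NUP), which build the nuclear pore, 14 were enriched and 1 depleted, with a median log2 ratio of 0.61 (camera adjusted p = 1.30e-04; adjusted p = 0.995 with an estimated correlation). NUP58 stood at 1.38, NUP153 at 1.22, NUP37 at 1.19 and NUP160 at 1.13, each with an SE of 0.10 or 0.11, while NUP214 was depleted at -0.42. Families that overlap the lists above also passed, RPL at a median of -0.29 (adjusted p = 0.00152), which turned to 0.35 without loess, and NDUFA at -0.66 (adjusted p = 0.0412), which stood at -0.0059 without loess, both with adjusted p = 0.995 with an estimated correlation. The nucleoporin median was 0.56 to 0.66 in the replicates and stayed positive under the other normalizations, from 0.58 with processed signals and median centring to 1.29 without loess. Of 16 protocadherin beta genes (PCDHB), cell adhesion molecules with near-identical copies, 10 were enriched and 6 did not pass (median 0.26, and 0.49 to 0.51 with processed signals; adjusted p = 0.0453; adjusted p = 0.995 with an estimated correlation).

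Of 415 zinc-finger genes named ZNF, 159 were enriched and 44 depleted (median 0.15, but 0.035 without loess and 0.29 to 0.32 with processed signals; camera adjusted p = 0.0453; adjusted p = 0.995 with an estimated correlation). Of 15 KLF transcription factor genes, 9 were enriched, led by KLF10 at 1.14, and 1 was depleted, KLF16 at -1.12, but the family did not pass (adjusted p = 0.0841). Of 12 SRSF splicing factor genes, 7 were enriched, SRSF3 and SRSF2 most at 2.11 and 1.102, and SRSF5 was depleted at -0.86, and again the family did not pass (adjusted p = 0.0841). Mitochondrial ribosomal proteins went both ways, with 8 of 28 MRPS genes enriched and 15 depleted, and 13 of 50 MRPL genes enriched and 22 depleted. MRPL50 and MRPL42 stood at 1.75 and 1.65, and MRPL41 and MRPS9 at -1.32 and -1.15. Neither family passed (adjusted p = 0.125 and 0.150), and their medians of -0.31 and -0.19 turned to 0.25 and 0.37 without loess.

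Genes of chromosome 19 lay lower in the Msi1 RIP than other genes. Of 1218 tested, 501 (41.1%) were depleted and 173 enriched, and their median of -0.15 lay 0.18 log2 units under that of the other chromosomes (a difference of -0.18, and of -0.25 to -0.41 under other normalizations). Within bins of equal brightness, 92.4% of the difference was left with loess (-0.17) and 96.9% with processed signals and loess. Loess removes a trend with brightness, and the medians of such bins had an SD of 0.033 in the main values. This argues against such a trend as the source of most of the difference of -0.18. In the values without loess, where a trend with brightness is still present, 76.9% of the difference was left (95% bootstrap interval 60.7% to 101%). That lies between the bounds set for and against an intensity trend, so a share due to one in those values cannot be told apart. Base composition is a candidate explanation, since each of 5 chromosomes of high GC content had a lower median than each of 6 of low GC content (100% of 30 pairs), with chromosomes 18, 13 and 4 highest at 0.12, yet the 200 zinc-finger genes on chromosome 19 had a median of 0.21 against -0.22 for the rest of it. Whether this reflects a preference of Msi1 for transcripts of low GC content, or a bias of amplification or hybridisation, was not tested, because no transcript sequences were used here.

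Whether 1 control RNA served both replicates was examined through the differences between slides. A shared control would have varied less between slides than the Msi1 RNA, and a ratio of their SDs of at least 1 had been set before the result was seen as the value that argues against it. The ratio was 1.00, with a 95% bootstrap interval over genes of 0.993 to 1.01, an interval added after the ratio was seen, so that this bound was met by less than its spread, and among genes brighter than the median it was 0.947. The slide differences of the RNAs correlated at 0.859 across genes, so what both channels of a slide share dominates them, and 1 or 2 control RNAs cannot be told apart.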
